A study of Mus musculus with 6 samples.

How the data were processed

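Messenger RNA sequencing reads of 4T1 cells (named 4T1_T in the title of the deposited table; the subline is not described) infected with a hairpin against Asns (shAsns-1 or shAsns-2) or with the control hairpin shRenilla were counted per gene. Per the labels, each hairpin had 2 libraries, A and B. The labels do not say whether A and B are separate cultures or infections, so p-values of single genes measure only the spread between these libraries. The deposited table held integer read counts for 23486 genes and 6 libraries, made by the authors. According to the submitters' processing notes, RNA was extracted with Trizol, libraries were made with the Nugen Ovation RNA-Seq V2 kit, reads were aligned to mm10 with Bowtie2 and counted with HTSeq. The versions of Bowtie2 and HTSeq, the annotation and the strand setting are not given in the sources used here. Read files were not analysed here.

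The column of shAsns-1 B was 0 at every gene and was left out. The design, which assumed 6 libraries, was therefore fitted to 5 with 2 residual degrees of freedom, and the lone shAsns-1 library was assumed to vary like the other groups. Asns was higher in that library than in shRenilla, against its label, so it is called the library labelled shAsns-1 throughout. No column was given to no sample. The tallies that HTSeq writes below the genes stayed out of library sizes and tests. In the order shAsns-1 A, shAsns-2 A and B, shRenilla A and B, reads that fell in no annotated feature made up 36.2, 37.6, 38.3, 38.2 and 36.1% of all reads, unaligned reads 23.2, 20.1, 18.2, 17.9 and 19.1%, and reads matching more than 1 gene 0.584, 0.596, 0.626, 0.623 and 0.620%. The tallies for reads with several alignments and for low alignment quality were 0 in every library. Reads with several alignments were thus not set aside, and levels of near-identical genes such as histones and ribosomal proteins are uncertain. Reads of the ribosomal RNA precursor Rn45s took 1.99 to 2.89% of the gene reads.

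Gene reads per library ranged from 10244753 to 15955168, so 3 reads, taken as the floor, correspond to 0.188 to 0.293 CPM (reads per 1000000 gene reads). The median SE of a log2 fold change was 0.112 for shAsns-2 against shRenilla, 0.142 for the library labelled shAsns-1 against shRenilla, 0.106 for both hairpins and 0.144 between the hairpins. The median absolute log2 fold change of called genes was 0.665, 0.553, 0.478 and 0.596 in the same order. Libraries of a group were not duplicates of each other (chi-square per degree of freedom 3.17 for shAsns-2 and 9.2 for shRenilla, over genes with at least 20 reads in the pair). With shAsns-2 A and B the same measure was 6.88 and 5.29 for shRenilla A, and 10.2 and 8.69 for shRenilla B. By this measure shRenilla A thus lay closer to both shAsns-2 libraries than to shRenilla B. Interval bounds on ratios of single libraries and on CPM cover counting error only.

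Counts were fitted with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr with its default minimums by group, which left 12457. Libraries were scaled with TMM factors, and 1 quasi-likelihood fit over all groups gave a common dispersion of 0.00388 (biological coefficient of variation 6.23%) and 14.7 prior degrees of freedom. Contrasts were both hairpins (mean of the shAsns groups) against shRenilla, each hairpin against shRenilla, and shAsns-2 against the library labelled shAsns-1. The last is called the difference between the hairpins, but with 1 library on that side it cannot separate hairpin from library. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are the log2 values of that fit at edgeR's default settings, and intervals are 95%. A prior count of 2 was used for log2 CPM only. Libraries A and B of different hairpins share only a letter, so they were not paired in the fit.

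Genes were named by a rule: Asns always; for both hairpins the 10 largest positive and 10 largest negative log2 fold changes among called genes with an average log2 CPM of at least 3 and every shAsns library on the same side of both shRenilla libraries; for the other contrasts the 5 highest and 5 lowest; and up to 4 members with the smallest adjusted p of lists that passed or held called genes. Predicted gene models and pseudogenes were left out. Results for 2 further genes are not reported here. Members of the ATF4 list and Vim, Fn1, Twist1, Snai1, Snai2, Zeb1, Zeb2, Cdh1, Cdh2 and Epcam could always be named; Snai2 and Cdh2 were too low to be tested. Of the 32 gene lists, none of which contains Asns, 28 had at least 5 tested members. They were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists within a contrast. The calls at the preset correlation rest on the assumption that members of a list vary nearly independently. Their p-values compare the members with the other genes and do not measure the spread between libraries. The tests, the naming rule, the lists and the alternatives were chosen before the data were examined, except the correction for GC content, the summed histone reads and the tests of explanations.

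Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (1 CPM in 4 libraries), the replicate letter as a block, each library left out, the hairpins as 1 group, only the 2 groups compared, a minimum absolute log2 fold change of 1, and removal of a smooth GC trend per library (loess, span 0.5, fitted above a log2 CPM of 3). GC content, exon length and positions came from GENCODE mouse release 21 on GRCm38 (mm10); 21911 symbols were found there directly and 1184 through a RefSeq synonym. Agreement of the hairpins was compared with 50 simulations in which both shAsns groups were unchanged draws against the same controls.

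The fit was tested on simulated data with 200 changed genes, drawn only from genes above a minimum average CPM, so recovery at lower genes was not tested. All libraries were drawn with the fitted dispersion. The rates thus do not test whether the lone shAsns-1 library varies like the other groups. For the library labelled shAsns-1, 67% of genes changed by 1.5-fold were recovered (12270 genes in the fit) and 94.5% of those changed by 2-fold (12254 genes), with 6.94% and 2.07% false calls. For shAsns-2, recovery was 90% at 1.5-fold (12268 genes) and 99% at 2-fold (12273 genes), with 6.74% and 6.60% false calls. A simulated shift of 0.3 in 1 list was found at the preset correlation (adjusted p = 1.4e-35, with 0 of 27 other lists) and missed at the estimated one (adjusted p = 0.139). A list not passed at the estimated correlation may thus still have shifted. Genes were drawn independently in that simulation, so it does not test false list calls where members vary together. The GC correction, tested on a simulated trend, took its Spearman correlation from -0.660 to -0.00137.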

Results

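4T1 is a mouse mammary carcinoma cell line. Messenger RNA was counted gene by gene in 4T1 cells, named 4T1_T in the title of the deposited table, that carried 1 of 3 short hairpin RNAs. The hairpins shAsns-1 and shAsns-2 are directed at Asns, the gene of asparagine synthetase, which makes asparagine from aspartate with glutamine as the nitrogen donor. shRenilla is a control directed at a luciferase that mouse cells lack. The comparisons ask which transcripts change when Asns is knocked down. Each hairpin had a library A and a library B in the labels, but the column of shAsns-1 B held 0 reads for every gene. The hairpin shAsns-1 was therefore represented by 1 library, and shAsns-2 and shRenilla by 2 each. Reads assigned to genes numbered 10244753 in the library labelled shAsns-1, 10472179 and 13888327 in shAsns-2 A and B, and 15955168 and 14287190 in shRenilla A and B. At least 1 read was found at 17672 genes in the library labelled shAsns-1 and at 15052 to 15392 genes in the other libraries. When these were thinned to the same 10244753 reads, they held reads at 14733 to 15374 genes. Olfactory receptor genes, which most cell types keep silent, took 41.5 CPM (reads per 1000000 gene reads) in the library labelled shAsns-1 (95% exact Poisson interval 37.6 to 45.6, over 1122 genes), against 7.99 to 11.9 in the other libraries. The filter on low counts left 12457 genes for testing.

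Asns was lower in shAsns-2 than in shRenilla and higher in the library labelled shAsns-1. The gene (ENSMUSG00000029752) lies on chromosome 6 of GRCm38 (mm10), from 7675169 to 7693254 on the minus strand, and its exons cover 2735 bases. In shAsns-2 it stood at 45.6 ± 1.31 CPM (SD, n = 2), which is 79.3% of the 57.5 ± 1.75 CPM in shRenilla (SD, n = 2). The log2 fold change in shAsns-2 was -0.34 (SE 0.0882), or 0.792-fold with a 95% interval of 0.696 to 0.902. That difference had an unadjusted p of 0.00146 in edgeR's quasi-likelihood test and an adjusted p of 0.216 over all genes tested. In the library labelled shAsns-1, Asns stood at 109 CPM, or 189% of shRenilla, which goes against the label. Its log2 fold change there was 0.92 (SE 0.101; 1.89-fold, 95% interval 1.63 to 2.19; adjusted p = 6.27e-05). The ratio of Asns in that library was 1.88 to shRenilla A (95% interval 1.72 to 2.05) and 1.94 to shRenilla B (1.77 to 2.13), counting error only. Between the hairpins, Asns was lower in shAsns-2 by a log2 fold change of -1.26 (SE 0.103, adjusted p = 5.96e-06). Averaged over both hairpins, the log2 fold change against shRenilla was 0.29 (SE 0.0800, adjusted p = 0.0771), and it turned to -0.34 without the library labelled shAsns-1.

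**Figure D1:**
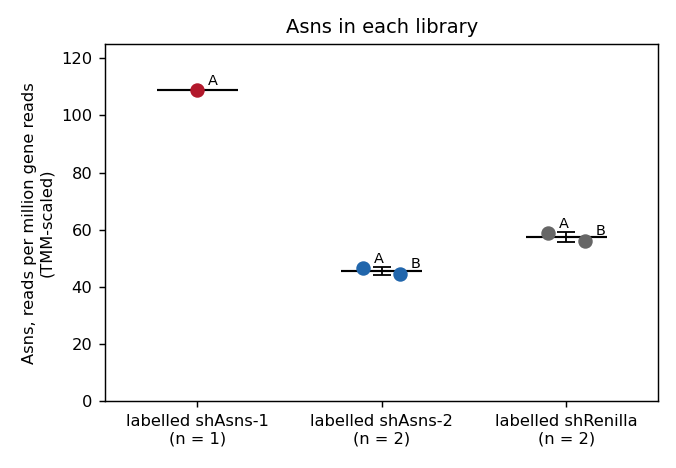
Asns in TMM-scaled CPM (vertical axis) in each library, by hairpin on the horizontal axis, with the group mean as a line and ± 1 SD where n = 2. The library labelled shAsns-1 stands at 109, above both shRenilla libraries (mean 57.5), and both shAsns-2 libraries lie below them (mean 45.6).

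In shAsns-2, compared with shRenilla, 8 genes rose and 0 fell. Slpi, which encodes a secreted inhibitor of leukocyte proteases, rose from 59.6 ± 5.05 to 99.6 ± 4.79 CPM (SD, n = 2 each; log2 fold change 0.74, SE 0.0892, adjusted p = 0.00331). Gng5, a G protein gamma subunit, rose from 45.7 ± 1.60 to 70.6 ± 3.67 CPM (0.62, SE 0.0885, adjusted p = 0.0133). Rplp1, an acidic protein of the ribosomal stalk, rose from 273 ± 9.25 to 381 ± 27.8 CPM (0.48, SE 0.0818, adjusted p = 0.0349). The other 5 genes encode histones that cells make during DNA replication: Hist2h3b (log2 fold change 0.87), Hist1h2bm (0.76), Hist2h3c2 (0.71), Hist2h3c1 (0.60) and the linker histone Hist1h1e (0.55), with adjusted p-values of 0.0235 to 0.0427. Hist1h1e, the most abundant of them, went from 197 ± 11.1 to 288 ± 28.9 CPM (SD, n = 2 each). Of these, 0 reached a 2-fold change. The direction was less one-sided in 2 other settings: 76.3% of called genes rose with no filter on low counts, and 75.3% with the replicate letter as a block. At an unadjusted p under 0.05, edgeR gave 696 genes up and 504 down where chance gives 311 in each direction. DESeq2 called 6 genes up and 0 down, and limma-voom called 7 up and 0 down. Of the genes on the histone list, DESeq2 called 2 against 4 by edgeR, and Hist1h2bm was among those lost (adjusted p = 0.685). Leaving out shAsns-2 A or shRenilla B left 0 genes called, and leaving out shRenilla A gave 47, with 3 of the 8 among them. Hist2h3b lost its call with the GC trend removed (0.74, adjusted p = 0.0563). Several histone genes have near-identical copies, so their single levels are uncertain.

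**Figure D2:**
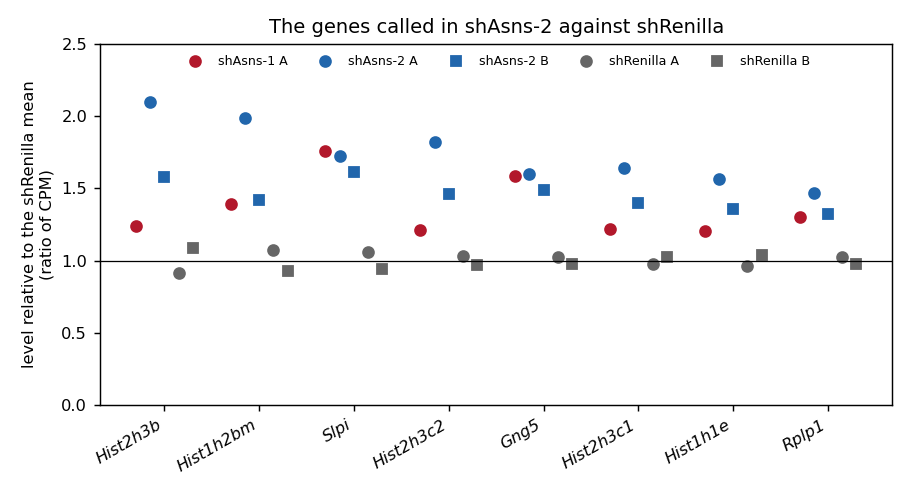
Level of the 8 genes that rose in shAsns-2, as the ratio of CPM in each library to the shRenilla mean (vertical axis, linear, from 0), with genes on the horizontal axis, circles for libraries A and squares for libraries B. Both shAsns-2 libraries lie above both shRenilla libraries for each of the 8 genes.

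Replication-dependent histones were higher as a group in shAsns-2. Of 49 histone genes measured on the list, which does not hold Hist2h3c2, 4 rose, 0 fell and 45 were not called; adjusted over the list alone, 11 rose. Their median log2 fold change was 0.24 (adjusted p = 4.79e-16), but the set test was not passed with an estimated correlation (adjusted p = 0.676 with an estimated correlation of 0.758 between members). It was not passed with fry either (adjusted p = 0.55). Without shRenilla A the median was 0.08 (adjusted p = 0.119), and without shRenilla B it was 0.49. Summed over the list, histone reads stood at 1657 and 1414 CPM in shAsns-2 A and B and at 1098 and 1414 CPM in shRenilla A and B. Rn45s, the ribosomal RNA precursor, and Rmrp, the RNA of RNase MRP, chosen after their values were seen, had log2 fold changes of 0.37 and 0.78 (adjusted p = 0.192 each), and like most replication-dependent histone transcripts they lack a poly(A) tail. Genes of the ATF4 and amino acid response, which cells induce when amino acids run short, had a median of 0.18 (32 genes, adjusted p = 2.88e-06). For that list the adjusted p was 0.44 with an estimated correlation and 0.0347 with fry. No member of that list passed over all genes tested, 3 rose when adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. Chac1, which breaks down glutathione, had a log2 fold change of 0.64 (SE 0.119, adjusted p = 0.0642), and Ddit4, an inhibitor of mTORC1 signalling, one of 0.69 (SE 0.131, adjusted p = 0.0674). Atf4 itself had a log2 fold change of 0.13, Trib3 0.38 and Ddit3 -0.30, all uncalled.

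In shAsns-2, of 77 ribosomal protein genes, Rplp1 rose and 76 were not called (8 up and 2 down adjusted over the list alone), with a median log2 fold change of 0.07 (adjusted p = 0.0102; adjusted p = 0.468 with an estimated correlation). That test was lost without shAsns-2 A (0.05, adjusted p = 0.164) or with no filter on low counts (0.07, adjusted p = 0.347). The 24 cholesterol synthesis genes had a median of 0.13 (adjusted p = 0.000433), with 0 called over all genes or adjusted over the list alone. Their adjusted p was 0.44 with an estimated correlation and 0.0347 with fry. Ribosome biogenesis and MYC targets had a median of -0.08 over 41 genes (adjusted p = 9.1e-05; adjusted p = 0.44 with an estimated correlation), with 0 called and 2 down adjusted over the list alone. Aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs, also had a median of -0.08 (20 genes, 0 called by either adjustment, adjusted p = 0.0119; adjusted p = 0.468 with an estimated correlation). Their test was lost without shAsns-2 A (-0.08, adjusted p = 0.0655) or shAsns-2 B (-0.10, adjusted p = 0.0765). Mesenchymal markers had a median of 0.08 over 43 genes (adjusted p = 0.0102; adjusted p = 0.703 with an estimated correlation), with 0 called and 1 up adjusted over the list alone. This test was lost without shAsns-2 A (0.05, adjusted p = 0.337) or shRenilla A (0.07, adjusted p = 0.0584). At an unadjusted p under 0.05, edgeR gave 6 cholesterol genes up and 0 down, 8 ribosome biogenesis genes down and 0 up, 1 synthetase down, and 5 mesenchymal markers up and 1 down. DESeq2 and limma-voom called 0 members of those lists and of the ATF4 list. Epithelial markers had a median of 0.01 and a mean of -0.03 (44 genes, 0 called by either adjustment, 6 up and 6 down at an unadjusted p under 0.05; set test towards lower values, adjusted p = 0.934; median -0.02 without shAsns-2 A), with Cdh1 at 0.08 and Epcam at 0.25.

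The library labelled shAsns-1, in which Asns was higher than in shRenilla and so against its label, differed from shRenilla at many more genes. Among them were epithelial genes and 2 laminin chains, all lower. Krt14, a keratin of basal epithelial cells, stood at 0.217-fold of shRenilla (log2 fold change -2.21, SE 0.237, adjusted p = 5.3e-05). Lama3, a chain of laminin-332, stood at 0.263-fold (-1.93, SE 0.181, adjusted p = 1.26e-05), and Lamb3, another chain of it, had a log2 fold change of -1.70 (SE 0.140, adjusted p = 7.1e-06). Wnt7a, a secreted Wnt ligand, stood at 0.238-fold, Esrp1, a splicing factor of epithelial cells, at 0.270-fold and Adam12, a membrane metalloprotease, at 0.294-fold. Phex, an endopeptidase with a role in phosphate balance, was 2.57-fold higher (log2 fold change 1.36, SE 0.0974, adjusted p = 1.5e-06). Cck, the peptide cholecystokinin, was 2.40-fold higher, Pdcd4, an inhibitor of translation, 2.32-fold, Sema4c, a semaphorin, 2.25-fold, and Mmp3, the metalloprotease stromelysin-1, 2.22-fold. In all, 288 genes were higher and 256 lower, 79 of them by at least 2-fold (31 higher, 48 lower). DESeq2 called 253 (130 higher, 123 lower). The lone library was assumed to vary like the other groups, and the count was 290 without shAsns-2 A, 302 without shAsns-2 B and 825 without shRenilla B. Across 7480 well-expressed genes, the log2 fold change fell with the GC content of the transcript (Spearman -0.359; genes are not independent replicates), against 0.0607 in shAsns-2.

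Of 44 epithelial markers measured in the library labelled shAsns-1, 17 fell, 0 rose and 27 were not called; adjusted over the list alone, 23 fell. The median log2 fold change was -0.51 (adjusted p = 5.42e-20; adjusted p = 0.152 with an estimated correlation). Besides Krt14 and Esrp1, these included Krt7 (-0.78), Dsp, the desmosomal protein desmoplakin (-0.96), Epcam (-0.69, adjusted p = 0.00259) and Cdh1, or E-cadherin (-0.48, adjusted p = 0.0135). Mesenchymal markers moved both ways, with 4 up, 5 down and 34 not called among 43 (7 up and 6 down adjusted over the list alone; median 0.02, adjusted p = 0.556; -0.05 without shRenilla B). Mmp3 (1.15), Mgp (1.14) and Zeb2 (0.43, adjusted p = 0.0204) rose, while Mmp9 (-1.70) and Fn1, or fibronectin (-0.64, adjusted p = 0.00554), fell. Vim (0.08), Twist1 (0.25), Snai1 (0.07) and Zeb1 (0.01) were not called. Epithelial and other lower lists were measured in a library that also carried more olfactory receptor reads (41.5 CPM) and the GC trend, with Asns against its label.

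**Figure D3:**
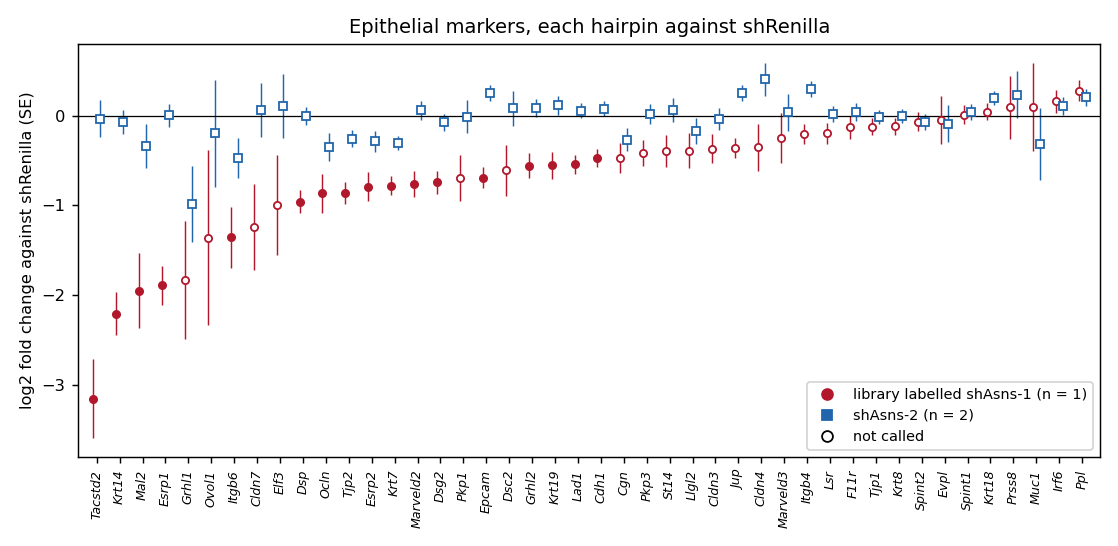
Log2 fold change against shRenilla (vertical axis, ± SE) of 44 epithelial markers on the horizontal axis, in the library labelled shAsns-1 (circles, n = 1) and in shAsns-2 (squares, n = 2), with open symbols for genes that were not called. 17 markers are lower in the library labelled shAsns-1 and 0 are called in shAsns-2.

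Further groups were lower in the library labelled shAsns-1, where Asns was higher against its label. Ribosome biogenesis and MYC targets had a median log2 fold change of -0.28, with 11 of 41 down, 0 up and 30 not called (24 down adjusted over the list alone; adjusted p = 1.66e-13; adjusted p = 0.152 with an estimated correlation). Rrp12 (-0.76), Heatr1 (-0.49) and Bysl (-0.54), factors of ribosome assembly, and Polr1b (-0.56), a subunit of RNA polymerase I, were among them. YAP/TAZ targets had 5 of 21 down, 0 up and 16 not called (9 down adjusted over the list alone; median -0.28, adjusted p = 1.94e-07; adjusted p = 0.152 with an estimated correlation). Cyr61 (-1.10) and Ctgf (-0.97), matricellular proteins that are also on the TGF-beta list, fell with Ajuba (-0.65) and Wwc1 (-0.66). TGF-beta response genes had 7 of 26 down, 0 up and 19 not called (10 down adjusted over the list alone; median -0.26, adjusted p = 5.95e-07; adjusted p = 0.152 with an estimated correlation). Inflammatory cytokines and NF-kB targets had 7 of 29 down, 0 up and 22 not called (9 down adjusted over the list alone; median -0.29, adjusted p = 4.65e-07; adjusted p = 0.152 with an estimated correlation), among them Cxcl16 (-1.27), Ptgs2, the inducible prostaglandin synthase (-0.68), Tnfaip3 (-0.74) and Il1a (-3.89). Aminoacyl-tRNA synthetases had a median of -0.24 with 0 of 20 called (3 down adjusted over the list alone, 12 down at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; adjusted p = 1.79e-05; adjusted p = 0.173 with an estimated correlation). Cholesterol synthesis genes had a median of -0.19 with 2 of 24 down, Hsd17b7 and Srebf2 (both -0.46), by either adjustment (adjusted p = 0.000715; adjusted p = 0.196 with an estimated correlation).

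Hypoxia response and interferon response genes were higher in the library labelled shAsns-1. Of 25 hypoxia genes, 4 rose, 0 fell and 21 were not called (11 up and 2 down adjusted over the list alone; median 0.23, adjusted p = 0.00198; adjusted p = 0.262 with an estimated correlation). Bnip3, a mitophagy receptor (0.88), Ankrd37 (1.36), the carbonic anhydrase Car9 (0.46) and the prolyl hydroxylase Egln3 (0.45) were the 4. Of 41 interferon genes, Gbp7 (0.73) and Ifit1 (1.72) rose and 39 were not called by either adjustment (median 0.18, adjusted p = 0.00198; adjusted p = 0.196 with an estimated correlation). Both tests were lost with no filter on low counts (adjusted p = 0.255 for hypoxia and 0.106 for interferon), and the interferon median was 0.29 without shRenilla B. The ATF4 and amino acid response list had a median of -0.06 (32 genes, adjusted p = 0.747), with Slc3a2, a heavy chain of amino acid transporters, down (-0.43, adjusted p = 0.0336, also adjusted over the list alone), 0 up and Atf4 at -0.01. Histones had a median of 0.11 with 0 of 49 called by either adjustment (6 up at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; set test adjusted p = 0.118). That test was passed at the preset correlation without shRenilla B (median 0.29) or with the GC trend removed (0.17), while the median turned to -0.06 without shRenilla A. In the main fit the histone test was not passed with an estimated correlation either (0.766 between members). In this library too, Asns went against its label.

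**Figure D4:**
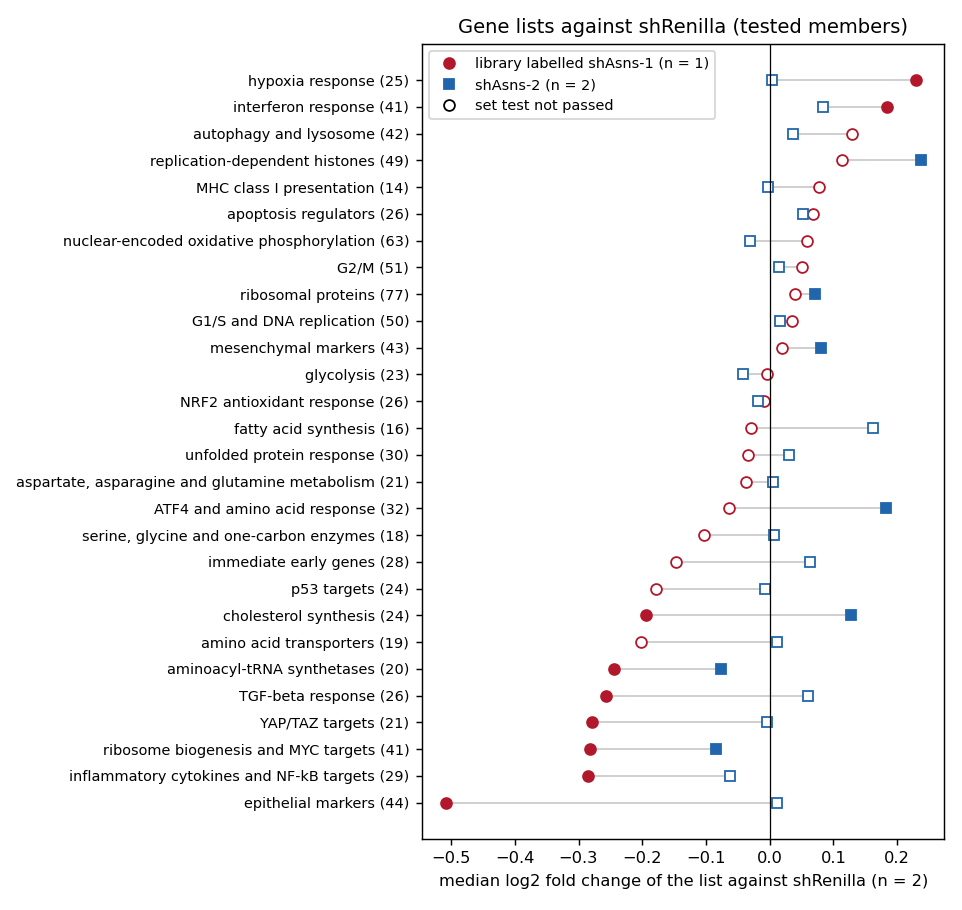
Median log2 fold change against shRenilla (horizontal axis) of 28 gene lists (vertical axis, tested members in parentheses) in the library labelled shAsns-1 (circles, n = 1) and in shAsns-2 (squares, n = 2), with filled symbols where the set test was passed at the preset correlation. Epithelial markers lie at -0.51 and 0.01, and histones at 0.11 and 0.24.

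The contrast of both hairpins together against shRenilla called 109 genes up and 86 down. The 10 genes with the largest increase by the naming rule were Mgp, an inhibitor of calcification (log2 fold change 0.92, SE 0.125, adjusted p = 0.000909), Pdcd4 (0.91), Phex (0.91), Sema4c (0.81), Cck (0.80), Tmie (0.78), Slpi (0.78, SE 0.0844, adjusted p = 0.000125), the cytokine Tslp (0.73), the neurotrophin receptor Ngfr (0.70) and Adamts9 (0.70). The 10 with the largest decrease by the same rule were Krt14 (-1.14, SE 0.154, adjusted p = 0.000909), Moxd1 (-1.09), the gelatinase Mmp9 (-1.03), Adam12 (-1.02), Gpr97 (-0.96), Rgs16 (-0.92), Fam83b (-0.91), Adamts1 (-0.89), Havcr2 (-0.86) and Sorbs2 (-0.77). Without the library labelled shAsns-1, where Asns went against its label, this contrast is the same as shAsns-2 against shRenilla. It then called 8 genes (8 up, 0 down), and of the 20 genes named only Slpi kept its call (0.74). Krt14 then had -0.07, Adam12 -0.28 and Phex 0.45, while Ngfr (0.79), Mgp (0.71), Tmie (0.69), Pdcd4 (0.60) and Fam83b (-0.63) lost the call with less change in value. At an unadjusted p under 0.05, 1020 genes were up and 983 down; DESeq2 called 99 (52 up, 47 down). Without shAsns-2 A the count was 77, and without shAsns-2 B it was 107. Taking all shAsns libraries as 1 group, with the hairpin ignored, left 1 gene called. Calls were also lost without shRenilla B for Adamts9 (0.48), Ngfr (0.58), Sema4c (0.58), Tmie (0.67) and Moxd1 (-0.87), and without shRenilla A for Ngfr (0.85) and Havcr2 (-0.85). Adamts9 lost its call without shAsns-2 A (0.69) or shAsns-2 B (0.71), and Ngfr without shAsns-2 A (0.66). DESeq2 did not call Adamts9 (adjusted p = 0.228), Ngfr (0.195) or Havcr2 (0.0934).

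Over both hairpins, 4 lists were higher and 6 lower than other genes, and 0 of the 28 set tests were passed with an estimated correlation, where the lowest adjusted p was 0.203. Of the lists passed at the preset correlation of 0.01, only histones (0.766) and hypoxia genes (0.0190) had an estimated correlation above it. For the others, correlated members do not account for the loss. Epithelial markers had 9 of 44 down (17 down and 1 up adjusted over the list alone; median -0.23, adjusted p = 8.36e-13). Ribosome biogenesis genes had 5 of 41 down (21 adjusted over the list alone; median -0.20, adjusted p = 5.78e-13), among them Polr1b (-0.45), Nolc1 (-0.39), Heatr1 (-0.35) and Rrp12 (-0.43). NF-kB targets (median -0.17, adjusted p = 9.1e-06), YAP/TAZ targets (-0.14, adjusted p = 4.55e-05) and TGF-beta response genes (-0.13, adjusted p = 0.000282) had 4 members down each, with 5, 6 and 8 down adjusted over the list alone (and 1 up among the TGF-beta genes). The 20 synthetase genes all had negative values, such as Cars (-0.29) and Wars (-0.28), with 0 called (2 down adjusted over the list alone; 7 down at an unadjusted p under 0.05; 0 by DESeq2 or limma-voom; median -0.15, adjusted p = 1.67e-05). Histones had 5 of 49 up (10 adjusted over the list alone; median 0.16, adjusted p = 2.83e-06), and their median was -0.02 without shRenilla A. Hypoxia genes had Bnip3 (0.51) and Ddit4 (0.56) up (4 up and 1 down adjusted over the list alone; median 0.14, adjusted p = 0.028), interferon genes had Gbp7 (0.52) up (2 adjusted over the list alone; median 0.11, adjusted p = 0.00398) and ribosomal proteins had Rplp1 (0.43) up (9 up and 2 down adjusted over the list alone; median 0.04, adjusted p = 0.0455). Without the library labelled shAsns-1, where Asns went against its label, only shAsns-2 against shRenilla remained. The medians were then 0.01 for epithelial markers, -0.05 for NF-kB targets, -0.00 for YAP/TAZ targets, 0.06 for TGF-beta genes, 0.00 for hypoxia and 0.08 for interferon genes, and all 6 tests were lost. The medians of ribosome biogenesis genes and synthetases shrank to -0.08 each without that library. Without shRenilla A the hypoxia (0.10) and interferon (0.10) tests were lost, without shAsns-2 B that of hypoxia (0.11), and without shAsns-2 A (0.02) or shRenilla B (0.03) that of ribosomal proteins. With the hairpins taken as 1 group, the tests of TGF-beta genes (adjusted p = 0.209), YAP/TAZ targets (0.0508) and hypoxia (0.209) were lost, and with no filter on low counts those of hypoxia (0.195) and ribosomal proteins (0.661).

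The shAsns-2 libraries were also compared with the library labelled shAsns-1. With 1 library on that side, a difference may belong to that library and not to its hairpin. Lama3 (4.83-fold, log2 fold change 2.27, SE 0.179, adjusted p = 5.96e-06), Krt14 (4.41-fold), Wnt7a (3.81-fold), Esrp1 (3.72-fold) and Lamb3 (3.19-fold) were higher in shAsns-2 than in the library labelled shAsns-1. Among genes with an average log2 CPM of at least 3, Asns, against the label of that library, had the lowest value (0.419-fold), followed by Mmp3 (log2 fold change -1.15), Cck (-0.94), Phex (-0.92) and Eno2, the neuronal form of enolase (-0.90, adjusted p = 0.0373). Eno2 lost its call without shAsns-2 B (-0.68, adjusted p = 0.236) or shRenilla A (-0.90, adjusted p = 0.0606). In all, 166 genes were higher in shAsns-2 and 101 lower, 41 of them by at least 2-fold. The count of 267 was 58 without shAsns-2 A, 108 without shAsns-2 B and 642 without shRenilla B, 156 with DESeq2 (114 higher, 42 lower) and 147 with the GC trend removed (104 higher, 43 lower). The log2 fold change followed GC content with a Spearman correlation of 0.433 across 7480 genes.

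Between the hairpins, 12 lists were higher and 2 lower in shAsns-2, again with 0 passed at an estimated correlation (lowest adjusted p = 0.135) and with Asns against its label in the other library. Epithelial markers had a median log2 fold change of 0.54, with 15 of 44 higher, among them Epcam (0.95) and Cdh1 (0.55; 24 higher adjusted over the list alone; adjusted p = 1.19e-22). Cholesterol synthesis genes had a median of 0.30, with 4 of 24 higher and 15 when adjusted over the list alone (adjusted p = 9.9e-10): Hsd17b7 (0.62), Srebf2, the sterol-responsive transcription factor (0.65), Cyp51 (0.56) and Sqle (0.39). The list lay at 0.13 in shAsns-2 and at -0.19 in the library labelled shAsns-1. TGF-beta genes (0.30; 7 of 26 higher, 10 adjusted over the list alone), YAP/TAZ targets (0.30; 5 of 21, 12), NF-kB targets (0.25; 4 of 29, 8) and ribosome biogenesis genes (0.23; 3 of 41, 7) were higher as well, with adjusted p-values of 3.14e-08, 5.51e-08, 4.03e-06 and 1.99e-07. In the ATF4 list, Chac1 was higher (0.86, adjusted p = 0.00922) and 31 genes were not called (3 higher adjusted over the list alone; median 0.21, adjusted p = 0.00115). Amino acid transporters had a median of 0.20 (0 of 19 called, 4 higher adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; adjusted p = 0.0145). The transporter test was lost without shAsns-2 A (0.19, adjusted p = 0.126). Synthetases had a median of 0.17 (0 of 20 called by either adjustment, 5 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; adjusted p = 0.00566). Fatty acid synthesis genes had Fasn, fatty acid synthase, higher (0.64; 1 of 16 by either adjustment; median 0.16, adjusted p = 0.00904). Immediate early genes had Cyr61 higher (0.89) and Dusp6 lower (-0.41; 3 higher and 1 lower adjusted over the list alone; median 0.22, adjusted p = 0.00616), and their test was lost with the GC trend removed (0.09, adjusted p = 0.113). Histones had a median of 0.15 (0 of 49 called by either adjustment, 8 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; adjusted p = 0.00327), which was lost without shAsns-2 A (0.03) or with the GC trend removed (0.05). Hypoxia genes were lower in shAsns-2 (median -0.16; 4 of 25 lower, 9 lower and 3 higher adjusted over the list alone; adjusted p = 0.00219), with Bnip3 at -0.73, and so were interferon genes (median -0.19; 0 of 41 called by either adjustment, 7 lower and 2 higher at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom; adjusted p = 0.0201). With no filter on low counts both of these tests, and that of the transporters, were lost.

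Slpi, Gng5 and Rplp1 rose with both hairpins, with log2 fold changes of 0.82, 0.67 and 0.38 in the library labelled shAsns-1, where Asns went against its label. Those 3 genes were the whole overlap: 0 genes were called down with both and 0 in opposite directions by edgeR, and DESeq2 and limma-voom also gave 3 up and 0 down. Some genes were called down with both when no filter on low counts was used, with the replicate letter as a block or without shRenilla A. In 50 simulations of unchanged groups against the same controls the overlap was 0. Those groups held no true change, so this cannot tell whether 3 shared genes exceed what shared controls give. Independent lists of these sizes would share 0.185 genes called up, a figure that leaves the shared controls out of account. The overlap was 0 without shAsns-2 A or without shRenilla B and 18 without shRenilla A. Of the 544 genes called in the library labelled shAsns-1, 199 were also called in the difference between the hairpins. Across 12457 genes the log2 fold changes correlated with r = 0.360, against a mean of 0.333 and a maximum of 0.372 in the simulations. The covariance was 0.0432, against a simulated 0.0191, a difference of 0.0241. The controls were not split between the hairpins, so part of the excess may come from the shared controls.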

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

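The tests of explanations for the 3 patterns weighed here (Asns, epithelial markers and histones) were chosen after those results were seen, while the tests of the difference between hairpins were fixed before.

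Asns was higher in the library labelled shAsns-1 than in shRenilla, against its label. An amino acid response through ATF4 is argued against by the other genes of that response, whose median log2 fold change was -0.0633 with 0 called up. An exchange with 1 shRenilla library is argued against by the ratio of Asns, at least 1.88 to each shRenilla library, while shRenilla A and B had similar levels. That ratio does not go against an exchange of the shAsns-1 and shRenilla labels as groups, in which shRenilla, at no more than 0.532 of that library, would be a knockdown; with 1 library on one side this stays open. It also stays open whether the library came from another culture or sample, since it stood apart. Its r with another library was at most 0.989, against at least 0.991 among the others. Chi-square per degree of freedom was 10.6 to 14.7 with the other libraries, against 3.17 to 10.2 among them. In it alone 1844 genes were seen, against 162 to 317 for each other library. Those 1844 genes held 2979 reads, or 0.0291% of its gene reads. An effect of its own hairpin could also set a library apart, but whether it would give reads at those genes was not tested.

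Epithelial markers were lower in the library labelled shAsns-1, where Asns was higher against its label. With the GC trend removed their median was still -0.44 (adjusted p = 1.01e-17) with 15 of 17 genes called again, which argues against that trend as the whole cause, though the set test without this removal had an adjusted p = 0.152 with an estimated correlation. The Asns transcript was not lower than in shRenilla (lower 95% bound of its log2 fold change 0.71). This restates that Asns was higher there and is no separate test. It does not cover the protein, and it holds only if the shAsns-1 and shRenilla labels were not exchanged as groups. What stays open is whether the pattern belongs to the hairpin, to 1 culture or to 1 library, because no other library carries this label.

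Replication-dependent histones were higher in shAsns-2 (adjusted p = 4.79e-16; adjusted p = 0.676 with an estimated correlation). None of the explanations tested was excluded. A larger share of cells in S phase was left undecided by the G1/S and DNA replication genes, whose median was 0.0162 with 26 of 50 positive. A different division of reads among near-identical copies would lower some members, whereas 46 of 49 were positive and the summed reads had a log2 ratio of 0.29, but it stays open because shAsns-2 B and shRenilla B had equal sums (1414 CPM) with 19 of 49 members higher in shAsns-2 B. More RNA without a poly(A) tail stays possible, with Rn45s at a log2 fold change of 0.37 and Rmrp at 0.78 (adjusted p = 0.192 each), both higher in each shAsns-2 library than in each shRenilla library.

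The shAsns-2 libraries differed from the library labelled shAsns-1 at 267 genes. With 1 library on that side, this cannot be told apart from a trait of that library alone, and the count changed widely when single libraries were left out. Lama3 (log2 fold change 2.27), Krt14 (2.14), Wnt7a (1.93), Esrp1 (1.89), Lamb3 (1.67), Rgs16 (1.51), Adam12 (1.48), Havcr2 (1.41), Mmp9 (1.35), Gpr97 (1.07), Adamts1 (1.03) and Sorbs2 (0.64) were higher in shAsns-2 than in the library labelled shAsns-1. Sema4c (-0.72), Tslp (-0.81), Eno2 (-0.90), Phex (-0.92), Cck (-0.94), Mmp3 (-1.15) and Asns (-1.26) were lower, Asns against the label. Of the lists, epithelial markers (median 0.54), cholesterol synthesis (0.30), TGF-beta response (0.30), YAP/TAZ targets (0.30), NF-kB targets (0.25), ribosome biogenesis and MYC targets (0.23), immediate early genes (0.22), ATF4 and amino acid response (0.21), amino acid transporters (0.20), aminoacyl-tRNA synthetases (0.17), fatty acid synthesis (0.16) and histones (0.15) were higher in shAsns-2, and interferon response (-0.19) and hypoxia response (-0.16) lower. All 14 of these list calls were lost with an estimated correlation (lowest adjusted p = 0.135). The library labelled shAsns-1 held olfactory receptor reads at 41.5 CPM. In the same library, 23.2% of reads were not aligned, the largest share of any library.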

How the results depend on the processing

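The correction for GC content was chosen after the data were seen; all other settings were fixed before.

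Counts of called genes moved most. With no filter they were 497 for both hairpins, 919 for the library labelled shAsns-1 (Asns against its label), 114 for shAsns-2 (87 up, 27 down, so 76.3% up against 100% before) and 608 for the difference, with an overlap of 39. DESeq2 gave 99, 253 and, for the difference, 156, of which 73.1% were up against 62.2%. Taking all shAsns libraries as 1 group left 1 gene. With a log2 fold change of at least 1 the counts were 14, 79, 0 and 41, with an overlap of 0. Fitting only the 2 groups compared gave 298 for the library labelled shAsns-1 and 812 for the difference, and the GC correction gave 147 for the difference. The cause of these moves was not tested.

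The replicate letter as a block, a pairing that the data do not carry (r = -0.0173 over 12457 genes from 2 pairs; 0.0300 over 7501 well-expressed genes), left 1 residual degree of freedom. Under this block the counts were 536, 924, 178 and 875 with an overlap of 43. Asns had 0.28 for both hairpins (adjusted p = 0.0439) and -0.33 for shAsns-2 (adjusted p = 0.0388), calls that the unpaired fit did not make, and the ribosomal protein test over both hairpins was lost (adjusted p = 0.0611) while that of histones in the library labelled shAsns-1 was gained (0.18, adjusted p = 0.0323).

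With each library left out in turn, counts ranged from 8 (without shAsns-1 A) to 187 (without shRenilla B) for both hairpins, 290 to 825 for the library labelled shAsns-1, 0 to 47 for shAsns-2 and 58 to 642 for the difference. The overlap ranged from 0 to 18 and the correlation of the hairpins from 0.270 to 0.502. Asns ranged from -0.34 to 0.33 for both hairpins, 0.89 to 0.95 for the library labelled shAsns-1, -0.37 to -0.30 for shAsns-2 and -1.28 to -1.23 for the difference. Medians over both hairpins ranged from -0.0440 to 0.13 for cholesterol synthesis, -0.26 to 0.0120 for epithelial markers, -0.15 to 0.0609 for TGF-beta genes and -0.0229 to 0.36 for histones.

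With an estimated correlation camera passed 0 lists in each of the 4 contrasts (both hairpins, the library labelled shAsns-1, shAsns-2 and the difference), against 10, 9, 7 and 14 at the preset. That test also missed a simulated shift of 0.3, so it does not show that the lists were unchanged. The counts with fry were 2, 10, 3 and 9 in the same order. In shAsns-2 the ATF4, cholesterol and fatty acid synthesis lists passed fry (adjusted p = 0.0347 each). Histones (0.55), ribosome biogenesis (0.0701), synthetases (0.159), mesenchymal markers and ribosomal proteins (0.322 each) did not. Each list median was compared with the main fit in each setting by its call, not its size. The call was unchanged in 1150 comparisons, lost in 31 and gained in 19, and 4 changed sign with a call in at least 1 fit. A change of sign without a call counted as unchanged, as for histones in the library labelled shAsns-1 (0.11, and -0.06 without shRenilla A). Among named genes 539 comparisons kept the call and 68 lost it, 19 of these without shAsns-1 A and 19 with the hairpins as 1 group. The GC correction ended the call of Hist2h3b in shAsns-2 (0.74, adjusted p = 0.0563). Depth limits what can be read at low genes, where the floor of 3 reads lies at 0.188 to 0.293 CPM. Among genes above a minimum average CPM, simulated 1.5-fold changes were recovered at 67% for the lone library and 90% for shAsns-2. Recovery at lower genes and the effect of depth on it were not tested.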

Other observations

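The lists described here and the asparagine test were written down before their results were seen; only the GC correction was chosen after.

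In the library labelled shAsns-1, where Asns was higher against its label, scattered members of further lists changed. Plk2, a p53-responsive kinase (log2 fold change -1.03), and Perp (-0.54) fell while the cyclin Ccng1 (0.41) rose among 24 p53 targets (median -0.18, set test adjusted p = 0.0862). 4T1 is known as a Trp53-null line, so changes in this list are not evidence of a response through p53. Gsta4 (0.46) and the glutathione reductase Gsr (0.41) rose and the heme oxygenase Hmox1 (-0.63) fell among 26 NRF2 genes (median -0.01, adjusted p = 0.910). Ccne2 (0.68) and Pcna (0.47) rose among 50 G1/S and DNA replication genes (median 0.04, adjusted p = 0.214), and Cad (-0.50) and Adsl (-0.45) fell among 21 genes of aspartate, asparagine and glutamine metabolism (median -0.04, adjusted p = 0.556). Single genes changed in oxidative phosphorylation (Cyc1 -0.45; 63 genes, median 0.06, adjusted p = 0.227), glycolysis (Eno2 0.78; 23 genes, median -0.00, adjusted p = 0.399), the unfolded protein response (Sec61b 0.42; 30 genes, median -0.03, adjusted p = 0.905), autophagy and lysosome (Lamp2 0.43; 42 genes, median 0.13, adjusted p = 0.0862), apoptosis regulators (Mcl1 0.38, 0 when adjusted over the list alone; 26 genes, median 0.07, adjusted p = 0.250), fatty acid synthesis (Fasn -0.47; 16 genes, median -0.03, adjusted p = 0.235) and amino acid transporters (Slc3a2 -0.43; 19 genes, median -0.20, adjusted p = 0.118). Rps20 (0.40) and Rplp1 (0.38) rose among 77 ribosomal proteins (median 0.04, adjusted p = 0.250; 0 when adjusted over the list alone), and Dusp6 (0.45) rose and Cyr61 fell among 28 immediate early genes (median -0.15, adjusted p = 0.0862). Serine, glycine and one-carbon enzymes (18 genes, median -0.10, adjusted p = 0.479), G2/M genes (51 genes, 0.05, adjusted p = 0.247) and MHC class I presentation (14 genes, 0.08, adjusted p = 0.123) had 0 called by edgeR, DESeq2 or limma-voom, with 4, 10 and 3 at an unadjusted p under 0.05. Single libraries moved several of these medians: without shRenilla B they were -0.04 for p53 targets, -0.13 for amino acid transporters and 0.01 for ribosomal proteins, and without shRenilla A 0.00 for one-carbon enzymes and 0.04 for aspartate, asparagine and glutamine metabolism. With the GC trend removed, the set tests at the preset correlation were passed for p53 targets (-0.12, adjusted p = 0.0463), autophagy and lysosome (0.13, adjusted p = 0.0101), MHC class I (0.12, adjusted p = 0.0359) and ribosomal proteins (0.08, adjusted p = 0.0239); an estimated correlation was not tried with the trend removed.

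In shAsns-2 edgeR, DESeq2 and limma-voom called 0 members of all these lists but the ribosomal proteins, and the medians lay near 0: -0.01 for p53 targets, -0.02 for NRF2 genes, 0.02 for G1/S, 0.01 for G2/M, -0.03 for oxidative phosphorylation, 0.03 for the unfolded protein response, 0.04 for autophagy and lysosome, 0.05 for apoptosis regulators, 0.01 for one-carbon enzymes, -0.00 for MHC class I, 0.06 for immediate early genes and 0.08 for interferon genes. Fatty acid synthesis genes had a median of 0.16 (adjusted p = 0.110 at the preset correlation, 0.0347 with fry), with 3 up at an unadjusted p under 0.05. Without shRenilla B their median was 0.08. For glycolysis the median was -0.04, the mean 0.03 and the set test pointed up (adjusted p = 0.934); for amino acid transporters the median was 0.01 and the mean -0.00 (test up, adjusted p = 0.673); for aspartate, asparagine and glutamine metabolism the median was 0.01 and the test pointed down (adjusted p = 0.917). Of leukocyte markers 1 was high enough to test (Cd68, -0.14), and of fibroblast and endothelial markers 3 (Tie1 0.62, Eng 0.19, Pdgfra 0.07), with 0 called. The mitochondrially encoded transcripts and the vector and reporter transcripts had 0 of 28 and 0 of 6 members in the table.

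If less asparagine synthetase limited asparagine, transcripts of asparagine-rich proteins might fall in shAsns-2, where Asns was lower. With the GC trend removed, the Spearman correlation between log2 fold change and the asparagine share of the protein was 0.0113 over 7451 genes, and asparagine ranked 16 of 20 amino acids from the lowest. Without that removal, which was chosen after the data were seen, it was -0.0255 over 7371 genes, with rank 10. Both values are close to 0, so no such relation was seen at the transcript level in shAsns-2. Asns there stood at 79.3% of shRenilla, and levels of asparagine in the cells were not analysed here. Whether asparagine was limited is thus unknown, and the test cannot decide what would follow if it were. An effect on translation stays open as well. Measuring asparagine and its tRNA charging under shAsns-2 would test it.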
